A study of Mus musculus with 12 samples.

How the data were processed

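H4K20me3 ChIP-seq was made from mouse embryonic stem cells at 4 times after addition of auxin and dTAG13, with 3 replicates per time. Per the labels' protocols, each immunoprecipitation used 24 μg of mouse chromatin, a Drosophila chromatin spike-in of 1.5 μg and 3 μg of antibody. Per the series description, the same libraries were sequenced in 3 runs, and inputs of the same samples served as controls; they are not used here. Bowtie2 2.3.4.1, SAMtools 1.1, deepTools and bedtools are named, per the submitters' processing notes, with the builds mm10, dm6, mm9 and GRCm38. The role of each tool and build is not given in the sources used here.

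The deposited file used here is 1 domain list of 3 columns (chromosome, start, end) without a header. The authors called its domains with RSEG, a segmentation tool for broad marks, per the file name; its version, its threshold and the libraries and times it was run on are not given in the sources used here. Tested on the file, the list holds 28210 domains without overlap. All but 1 have both boundaries on a grid of 150 bases, and the smallest gap between neighbours is 750 bases. Contig names are those of mm10. The authors' processing thus leaves positions only, per the file, with no signal to scale or filter. No sample is named in the list, so the grouping of the 12 samples by time enters no test. The depth of each library is unknown here, so no interval for counting error can be given. The planned comparison of times and the planned relation of domain width to score were not run, because the list holds neither.

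Genes came from a RefSeq gene table of assembly GRCm38.p6, which is mm10, with start, end, symbol and biotype but no strand, exons or sequence. Of 49997 genes, 49214 on chromosomes 1 to 19 and X were used, 21523 of them protein-coding. Left out were 340 genes with a start in the first 3 Mb, whose positions were taken to refer to unplaced scaffolds, and 443 genes on Y, the mitochondrial genome or no chromosome. For want of exons, strand and sequence, 3 planned analyses were not run: the last exon against the promoter of zinc finger genes, the sequence content of domains, and windows around transcription starts. Annotation classes were limited to gene bodies for the same reason, which departs from the plan. Chromosome ends were taken as the last annotated gene end or domain end.

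Coverage by chromosome, widths and position are descriptive. Clustering was tested by the variance-to-mean ratio of domain counts in 1 Mb windows against 1000 random placements of the same domains within chromosomes. Gene lists were tested by moving all domains together along each chromosome, on a circle from 3 Mb to the chromosome end, with 10000 shifts and a fixed seed. A gene counted when it shared at least 1 base with a domain. The two-sided p was 2 times the smaller tail with a correction of 1, and p values were adjusted by Benjamini-Hochberg over the 17 lists. Annotation classes used 1000 shifts and adjustment over 3 classes. For length matching, as many other protein-coding genes as list members were drawn 10000 times within 20 length bins, with list members left out. A bin with fewer other genes than members gave all it had. A list whose geometric mean length differed by more than 2 times from that of its matched genes was left out, which applied to the long neuronal genes, and p values were adjusted over the other 16 lists. The lists, the tests and most other settings were fixed before the data were examined. Those settings were domains closer than 5 kb merged, domains at or above the median width, autosomes only, 5 Mb windows, at least 50% of a gene body covered, Fisher's exact test against other protein-coding genes, neighbours within 200 kb counted as 1, all annotated genes, and 10 Mb chromosome ends. Added after the data were seen were the list without domains that begin at the first base, windows of 1 kb either side of both gene ends, and length matching. Symbols of the zinc finger list follow a naming rule, so members without a KRAB domain are included.

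Genes named in the text follow a rule fixed beforehand: the 10 widest domains with their protein-coding genes, the 10 protein-coding genes with the most covered bases, up to 4 members per list with the largest covered share, and Suv39h1, Suv39h2 and Setdb1. Other genes and windows are marked as chosen after their values were seen.

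The shift test was tested on simulated data. With domains placed at random in 40 simulations, 3.53% of 680 list tests had p under 0.05. With 20 or 60 genes of a list of 200 given a domain, 75% and 100% of 20 simulations had p under 0.05, with mean ratios of 1.26 and 1.74. The simulated domains were placed independently of each other, unlike the clustered domains of the list. Planted domains tested only overlap above expectation, so the power to find overlap below expectation was not simulated. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.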

Results

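H4K20me3, a histone mark of heterochromatin, was profiled by ChIP-seq in mouse embryonic stem cells of the line dTKO, whose labels give the genotype Suv39h1fl/fl; Suv39h2-/-; Setdb1fl/fl. Suv39h1, Suv39h2 and Setdb1 encode histone H3 lysine 9 methyltransferases. Auxin at 100 μg/ml and dTAG13 at 0.5 μM were added for 0, 12, 24 or 48 h, with 3 replicates at each of the 4 times and 12 libraries in all. The series asks how H4K20me3 decays once the H3K9 methyltransferases are ablated. The values analysed here were 1 list of 28210 H4K20me3 domains on the mouse build mm10, with a chromosome, a start and an end for each domain. The list carries no signal, score or sample name, so the decay over time, the depth of each library and the error between replicates could not be measured, and every value below describes that 1 list.

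The listed H4K20me3 domains were numerous and mostly short, with a small number of very wide blocks, chiefly on X, on Y and over unsequenced chromosome starts. The 28210 domains covered 133.6 Mb. Of these, 28177 lay on chromosomes 1 to 19 and X and covered 132.4 Mb, or 5.03% of their length. Without the domains over unsequenced chromosome starts, the share was 4.46% of the same length, which still includes those starts. The median width of all 28210 domains was 3.00 kb, with quartiles of 1.80 and 4.80 kb, and 2035 domains (7.21%) were wider than 10 kb. Only 21 domains exceeded 100 kb.

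The 5 widest domains began at the first base of chromosomes X, 7, 5, 8 and 1, were 3000 to 3058 kb wide and overlapped none of the genes used. Genes with a start in the first 3 Mb had been left out. They held 15.1 Mb, or 11.3% of all domain bases, and 99.6% of that length lay in the first 3 Mb, which is unsequenced in mm10. The next widest lay on Y, from 5369551 to 5957550 (588 kb), over the protein-coding gene Gm20914, and another on Y, from 9826801 to 10168650 (341.9 kb), over Gm21301 and Gm21310. The other 3 of the 10 widest stood side by side on X, at 124566151 to 124935150 (369 kb), 124941151 to 125367900 (426.8 kb) and 125372701 to 125628150 (255.5 kb), and overlapped no protein-coding gene. These 3 belonged to a run of 8 domains over 100 kb that covered 96.6% of X from 124250251 to 126065550, and each of the 8 held an annotated Rps12 pseudogene.

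Among protein-coding genes, Atg4a, an autophagy protease gene on X (140953845 to 141164194), had the most covered sequence, 160.8 kb in 1 domain, which was 76.4% of its body. Sgms2, a sphingomyelin synthase gene on chromosome 3 (131318985 to 131491443), had 93.6 kb covered by 3 domains, 54.3% of its body. The other 8 of the 10 genes with the most covered bases were long genes with many separate domains and a covered share of at most 15.4%. Sntg1, on chromosome 1, had 29 domains and 104.1 kb covered, and A830018L16Rik, on the same chromosome, had 18 domains and 86.7 kb. Fhit had 24 domains and 81.2 kb, Il1rapl2 9 domains and 80.1 kb, and Dmd, the dystrophin gene, 20 domains and 77.0 kb. Naaladl2 (76.4 kb), Pcdh15 (70.1 kb) and Agbl4 (67.8 kb) completed the set.

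The X chromosome carried more H4K20me3 domain sequence than any autosome. After the first 3 Mb, 9.26% of X lay in domains, against 2.69% of chromosome 19 and 5.43% of chromosome 4, the lowest and highest autosomes. Domains on X were also closer together, at 14.6 per Mb against 7.63 on chromosome 11 to 13.4 on chromosome 1, and wider, with a median of 3.90 kb against 2.55 to 3.15 kb on the autosomes. With the domains that begin at the first base included, coverage was 10.9% on X and 6.78 to 7.00% on chromosomes 1, 5 and 7, and chromosome 8 had 6.60%. Chromosome 1 held the most domains, 2569, followed by X with 2443. No replicate error exists for these shares.

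**Figure D1:**
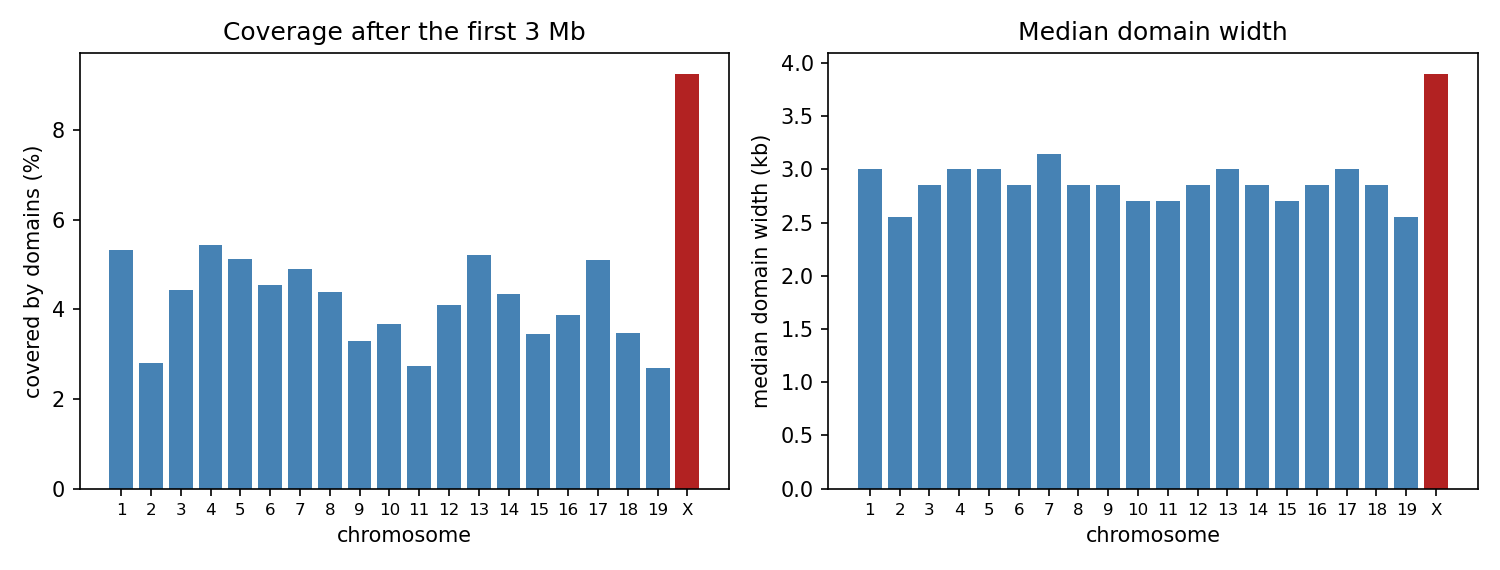
Bars give, for each chromosome, the percentage covered by domains after the first 3 Mb (left) and the median domain width in kb without domains that begin at the first base (right). X stands at 9.26% and 3.90 kb, above every autosome in both panels.

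Domains were gathered in some regions and thin in others. The densest 1 Mb window, on chromosome 4 from 60 to 61 Mb, held 45 domains and 260.4 kb of domain sequence. The window contained 10 Mup genes, which encode major urinary proteins. The next window, from 61 to 62 Mb, held 39 domains and contained more Mup genes. Of 22 genes named Mup, only 3 overlapped a domain (1.11 times the shifted mean), so most of them met none. On chromosome 13, the window from 22 to 23 Mb, where Vmn1r vomeronasal receptor genes lie beside a few histone genes, had 40 domains, and the window from 66 to 67 Mb, which includes Zfp640, had 39. Gene-poor windows were as dense. The window from 117 to 118 Mb on chromosome 1 had 43 domains and 1 protein-coding gene, B020011L13Rik. The window from 7 to 8 Mb had 40 domains and 1 such gene, Pcmtd1, and the windows at 4 to 5 Mb of chromosome 3 and 80 to 81 Mb of X had 38 and 36 domains and no protein-coding gene. These windows were named after their values were seen. Across 2581 windows of 1 Mb the median was 9 domains, and 32 windows had none. The variance-to-mean ratio of the counts was 4.80, against a mean of 1.32 and a highest value of 1.41 in 1000 random placements within chromosomes (one-sided permutation p = 0.001, the smallest these placements can give).

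Protein-coding genes lay largely outside the domains. Of 21523 such genes, 3044 (14.1%) overlapped a domain by at least 1 base, against 5861 ± 90.9 (SD over shifts) when all domains were moved together along each chromosome, a ratio of 0.519 (two-sided permutation p = 0.0002, the smallest that 10000 shifts can give). Protein-coding gene bodies took 16.6% of domain bases, against 38.7% ± 0.735 (SD) in 1000 shifts. Bodies of long noncoding RNA genes took 6.02%, against 8.17% ± 0.273. Pseudogenes went the other way, with 1.88% of domain bases against 1.13% ± 0.0982. The adjusted permutation p was 0.002 for each of these 3 classes, the smallest that 1000 shifts can give. Only 159 protein-coding genes had at least 50% of their body covered, against 435.8 ± 29.8 in the shifts.

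Much of the separation of domains and genes was local, and part of it extended over megabases. Moving the genes by 1 kb raised the number that met a domain from 3044 to 3098 (to the right) or 3117 (to the left). At 10 kb the numbers were 3893 and 3980, at 100 kb 4996 and 4933, at 1000 kb 5445 and 5438, and at 2000 kb 5596 and 5376, still below the shifted mean of 5861. The positions in the annotation thus gave the lowest count of all distances tried.

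**Figure D2:**
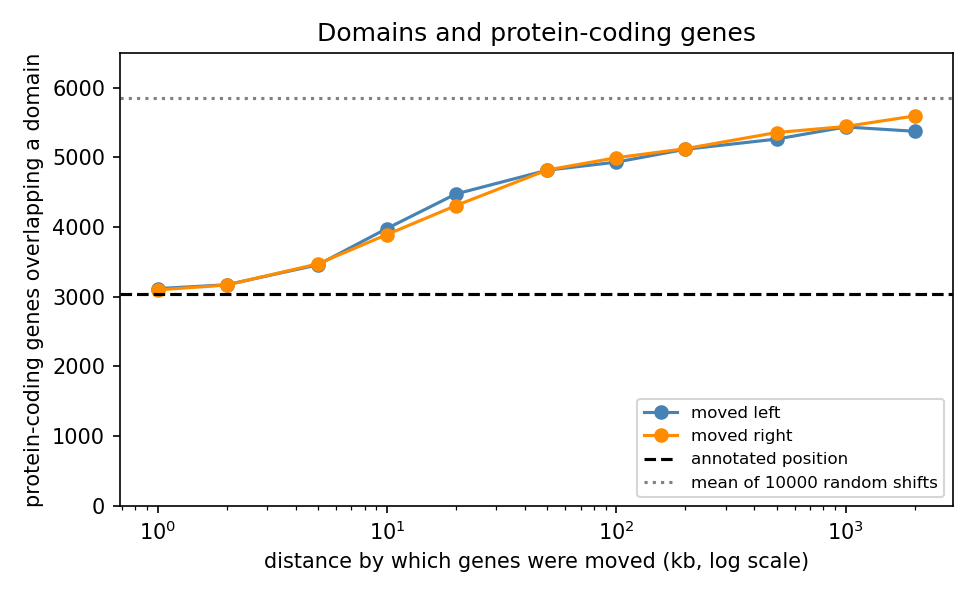
Points give the number of protein-coding genes that overlap a domain after all genes are moved by the distance on the x axis (kb, log scale), to the left or right. The dashed line marks 3044 genes at the annotated positions and the dotted line the mean of 10000 random shifts, 5861.

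Of the 17 gene lists fixed before the data were examined, 6 overlapped fewer domains than shifted positions did and none overlapped more, at an adjusted permutation p under 0.05. The 6 were zinc finger genes, olfactory receptor genes, bivalent developmental regulators, pluripotency genes, heterochromatin factors and X-linked multicopy testis genes. At an unadjusted p under 0.05 the counts were also 6 below and 0 above. Since protein-coding genes as a whole stood at 0.519 of the shifted mean, each list but the long neuronal genes is also given against other protein-coding genes of like length, a comparison chosen after the data were seen. That comparison draws other genes one by one and takes no account of clustering along chromosomes.

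Genes of the KRAB-type zinc finger list, taken by symbol whether or not they have a KRAB domain, met a domain in 70 of 424 cases (16.5%). This was below the shifted mean of 106.6 ± 11.0 (ratio 0.657, adjusted permutation p = 0.00680), but above the 46.1 ± 5.83 found for length-matched protein-coding genes (ratio 1.52, adjusted p = 0.0008). Against shifts, the call was lost for at least 50% of the body covered (0.885, adjusted permutation p = 1) and at 1 kb either side of gene ends (0.828, adjusted permutation p = 0.557). Fisher's exact test gave 1.17 (adjusted p = 0.246). Zfp996 on chromosome 12 had 91.6% of its body covered, Zfp629 88.9%, Zfp575 85.3% and Zfp640 67.7%. In all, 7 members were covered over at least 50% of their length.

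Germline genes overlapped domains in 15 of 34 cases (44.1%), the largest share of any list but the long neuronal genes. The shifted mean was 11.3 ± 2.54 (ratio 1.32, adjusted permutation p = 0.341), and length-matched genes gave 5.73 ± 2.02 (ratio 2.62, adjusted p = 0.0008). Rpl10l, a retrogene copy of a ribosomal protein gene, was covered over 73.4% of its body and Tex13b over 27.0%. Mov10l1, a helicase of the piRNA pathway, was covered over 18.2% by 2 domains, and Dmc1, the meiotic recombinase gene, over 10.3%.

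Genes of clustered xenobiotic and secreted proteins overlapped domains in 62 of 221 cases (28.1%). The ratio was 1.21 to shifted positions (adjusted permutation p = 0.341) and 2.98 to length-matched genes (adjusted p = 0.0008). With neighbours within 200 kb counted as 1, 18 of 38 clusters met a domain, 0.979 of the shifted mean. The matched p takes neighbouring members as independent, so it does not show an excess over clusters. Serpina3j (38.5% covered), Mup20 (35.0%, 4 domains), Cyp2j13 (33.1%) and Serpina9 (29.9%) had the largest covered shares. No member was covered over at least 50% of its body, where shifts gave 5.55 ± 3.01 (adjusted permutation p = 0.151). Vomeronasal receptor genes overlapped in 50 of 350 cases, 1.05 times the shifted mean (adjusted permutation p = 0.853) and 2.64 times the length-matched mean (adjusted p = 0.0008). Of 47 vomeronasal clusters, 24 met a domain, 1.04 times the shifted mean, and the same limit holds for the matched p of these genes. Their matched genes include olfactory receptor genes, which have a like median length (0.951 against 0.960 kb) and met a domain in 2.81% of cases. Fisher's exact test against all other protein-coding genes gave 1.01 (adjusted p = 0.997). Vmn1r48 and Vmn1r215 lay wholly inside domains, while Vmn2r85 was covered over 56.7% and Vmn1r1 over 54.1%. Only 5 of the 350 vomeronasal genes were covered over at least 50% of their body, against 12.9 ± 4.93 in shifts (ratio 0.387, adjusted permutation p = 0.342).

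Olfactory receptor genes stood below the mean of both comparisons, of which the matched one is limited. Only 31 of 1105 (2.81%) met a domain, 0.508 of the shifted mean (adjusted permutation p = 0.0187) and 0.721 of the length-matched mean (adjusted p = 0.00256). The matched draw may have run out of other short genes. Its mean may then stand for fewer than 1105 genes and its spread may be too small, so the matched p is not a separate support. When neighbours within 200 kb were counted as 1 cluster, 19 of 63 clusters met a domain, 0.818 of the shifted mean (adjusted permutation p = 0.392), so the call rests on counting single receptors, and it was also lost for domains at or above the median width, where the ratio was 0.479 (adjusted permutation p = 0.0544), and at 1 kb either side of gene ends, where it was 0.642 (adjusted permutation p = 0.213). Olfr318, Olfr761, Olfr1047 and Olfr1045 lay wholly inside domains.

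Pluripotency genes met a domain in 2 of 36 cases, 0.241 of the shifted mean (adjusted permutation p = 0.0187). The 2 were Sox2, a core pluripotency factor, with 0.900 kb covered (36.5%), and Stat3, the effector of LIF signalling, with 3.15 kb (5.97%). Bivalent developmental regulators met one in 4 of 55 cases, a ratio of 0.387 (adjusted permutation p = 0.0414). They were Neurod1 (18.8% covered), Gata2 (15.98%, 3 domains), Foxa1 (14.2%) and Gata4 (2.27%). X-linked multicopy testis genes overlapped in 4 of 80 cases, a ratio of 0.248 (adjusted permutation p = 0.0211), and these were Rhox2e, Xlr5c, Mageb18 and Luzp4, with 31.3%, 19.6%, 10.5% and 7.22% covered. With neighbours within 200 kb counted as 1, these testis genes stood at 0.515 (adjusted permutation p = 0.223) and bivalent regulators at 0.390 (adjusted permutation p = 0.0637), and with domains at or above the median width the testis genes stood at 0.310 (adjusted permutation p = 0.113) and pluripotency genes at 0.190 (adjusted permutation p = 0.110), so these calls were lost. At 1 kb either side of gene ends, pluripotency (adjusted permutation p = 0.333), bivalent (0.0510) and testis genes (0.0969) all lost the call. Bivalent regulators also lost it on autosomes (0.398, adjusted permutation p = 0.0602). Under Fisher's exact test, pluripotency (adjusted p = 0.295) and bivalent genes (0.248) lost it, while testis genes kept it (0.0319). Against length-matched genes, the ratios of these 3 lists were 0.534, 0.907 and 0.948, with adjusted p of 0.820, 1 and 1. Matching took no account of chromosome. For the X-linked list it gave 4.22 ± 1.84, where shifts kept on X gave 16.1 ± 6.18, so 0.948 is not a comparison with genes of X.

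**Figure D3:**
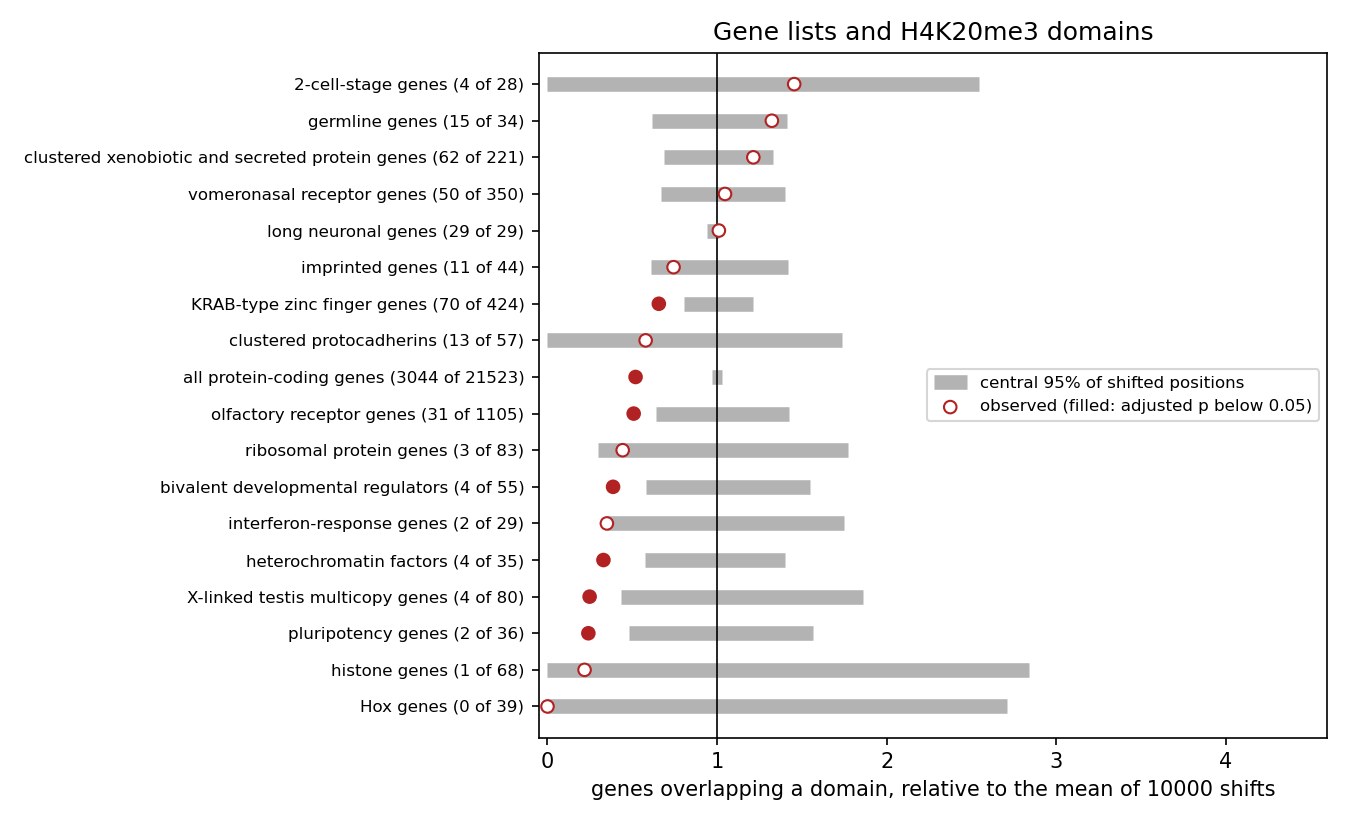
Circles give the number of genes of each list that overlap a domain, relative to the mean of 10000 shifts; filled circles have an adjusted p below 0.05, and grey bars span the central 95% of shifts. All protein-coding genes stand at 0.519 and zinc finger genes at 0.657, while germline genes stand at 1.32 inside the range of the shifts.

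Heterochromatin factors met a domain in 4 of 35 cases, 0.330 of the shifted mean (adjusted permutation p = 0.0102), and 2 of the 3 methyltransferase genes in the genotype of this line, Suv39h1 and Setdb1, were among the 4. Suv39h1 (X, 8061171 to 8074760) had 2 domains that covered 5.70 kb, 41.9% of its body. Setdb1 (chromosome 3, 95323525 to 95357202) had 6 separate domains of 0.600 to 2.25 kb that covered 6.30 kb, or 18.7%. Suv39h2 (chromosome 2, 3455815 to 3474986), which the genotype gives as null, had none. Cbx1, which encodes an HP1 protein, had 2 domains (6.65% covered), and Dnmt3l, a cofactor of DNA methylation, had 1 (4.92%). Against length-matched genes the list stood at 0.691 (adjusted p = 0.820), at 1 kb either side of gene ends at 0.701 (adjusted permutation p = 0.886), and under Fisher's exact test at 0.808 (adjusted p = 0.919), so the call was lost in each.

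The remaining lists did not pass the test against shifted positions. No Hox gene of 39 met a domain, where shifts gave 3.69 ± 2.52 (adjusted permutation p = 0.306). Among 83 ribosomal protein genes, 3 did, namely Rpl39l (75.4% covered), Rpl10l and Rpl15 (9.48%), and among 68 histone genes only H1f7, a testis-specific linker histone gene, did (75.9%). Imprinted genes overlapped in 11 of 44 cases, a ratio of 0.743 (adjusted permutation p = 0.397). The largest shares were in Kcnq1ot1, an imprinted noncoding RNA (29.8%, 24.9 kb), H19 (28.5%), Cdh15 (18.9%) and Kcnq1 (7.78%), which contains Kcnq1ot1. Genes of the 2-cell stage overlapped in 4 of 28 cases, a ratio of 1.45 (adjusted permutation p = 0.677), and the 4 were Tdpoz1 (19.4%), Zscan4b (18.8%), Zfp352 (16.6%) and Obox3 (10.4%). Clustered protocadherins overlapped in 13 of 57 cases, a ratio of 0.579 (adjusted permutation p = 0.531). Pcdha12, Pcdha11, Pcdha10 and Pcdha9 each had the same 6.60 kb covered, since their bodies overlap, which was 3.478 to 3.942% of their length. Interferon-response genes overlapped in 2 of 29 cases, Mx1 (12.3%) and Ifi44 (3.16%), a ratio of 0.350 (adjusted permutation p = 0.265). Against length-matched genes, the 2-cell-stage list had the highest ratio of all lists compared, 4.26, from 4 genes against 0.939 ± 0.960 (permutation p = 0.0292, adjusted p = 0.0779). The other ratios were 1.22 for imprinted, 0.813 for protocadherin, 0 for Hox, 1.08 for ribosomal protein, 0.494 for histone and 0.919 for interferon-response genes, with adjusted p from 0.688 to 1.

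All 29 long neuronal genes contained a domain, as 28.7 ± 0.557 did in the shifts (adjusted permutation p = 1), since their median length was 1375 kb. The covered share was highest in Il1rapl2 (6.27%), Magi2 (3.91%), Csmd1 (3.73%) and Pcdh11x (3.63%). They were on average 4.19 times as long as the protein-coding genes that length matching could offer, so no matched value is given.

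Domains covered a larger share of autosomal sequence beside centromeres than at the far chromosome ends. Mouse autosomes have the centromere at one end, so the first assembled bases border pericentromeric repeats. The first 5 Mb after the unsequenced start were covered to 7.59% over 19 autosomes, the last 5 Mb to 3.44%, and the whole to 4.24%. The first 5 Mb exceeded the chromosome's own mean on 15 of 19 autosomes. Coverage there was 14.6% on chromosome 3, 13.4% on chromosome 1 and 12.4% on chromosome 9, but 0.447% on chromosome 14, 1.46% on chromosome 19 and 2.14% on chromosome 17. On these last 3 the far end was covered more, to 4.20%, 1.90% and 6.43%. On every other autosome the first 5 Mb were covered more than the last. The last 5 Mb lay below the chromosome's mean on 15 of 19.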

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

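The tests on wide domains and on the methyltransferase genes in this part were chosen after the values were seen; those on X were set before theirs were. No explanation from the times of the design was tested for any of these patterns, since the list is not split by time.

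Domains also lay on sequences outside every comparison with genes. On chromosome Y there were 4 domains with 998.4 kb in all, and on 17 unplaced contigs there were 29 domains with 165.6 kb. They are listed because no comparison with genes used them; no control sample sets a level for them, and whether they exceed chance was not tested.

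The 2 methyltransferase genes that the genotype lists as floxed, Suv39h1 and Setdb1, held sets of domains that were rare in number, less so in covered share. None of 7243 other protein-coding genes from 50% to 2 times the length of Setdb1 (0 genes) held as many as its 6 domains, and 33 of 7463 genes near the length of Suv39h1 held as many as its 2, while 190 and 60 of these genes, respectively, had as large a covered share. A candidate explanation is extra copies of the edited coding sequences, such as degradable versions carried elsewhere in the genome, whose reads would fall on the exons of the native gene. The count of 0 genes shows how rare the pattern is but cannot separate this from H4K20me3 at the genes themselves, because exon positions are not in the gene table used. Suv39h2, given as null, held no domain, as did 91.4% of the 7857 genes near its length.

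Among the widest domains, the 5 that begin at the first base of a chromosome had 99.6% of their length in the first 3 Mb. That stretch is unsequenced in mm10, so no aligned reads lie behind these domains there. The 15 other chromosomes had no such domain. After the first 3 Mb, 14 domains exceeded 100 kb on chromosomes 1 to 19 and X, and 7.89% of their bases lay in annotated gene bodies against 34.0 ± 15.5% (SD) in 1000 shifts (permutation p = 0.0220). Unsequenced gaps or gene-poor sequence could both give this and cannot be told apart without the sequence. Outside the block on X, 3 of 6 such domains overlapped an annotated gene. Most of the bases in gene bodies came from 1 of them, the domain of 160.8 kb inside Atg4a. In the block on X, 8 of 8 domains (100%) held an Rps12 pseudogene, and 9 of the 23 annotated Rps12 pseudogenes lay in the block. Reads shared between repeated copies may therefore widen these domains, and marked repeats would give the same list.

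X had higher coverage than every autosome. Without domains over 50 kb, 7.84% of X was covered after the first 3 Mb against 5.30% of chromosome 1, the highest autosome, so a few wide domains do not account for the difference. Low gene density, counted as protein-coding genes per Mb, does not either. By the same measure, without domains over 50 kb, X lay 3.49 percentage points above the line fitted to autosomes. The highest autosomal residual was 1.29. X had 5.74 such genes per Mb, just below the lowest autosome (5.79), so the line was extended slightly to reach it. Chromosomes 12, 18 and 1, the nearest to X in gene density, were covered to between 3.41 and 5.30% by that measure. A different number of DNA copies of X and autosomes was not tested and stays open. The share of X in gene bodies and its sequence content were not tested either.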

How the results depend on the processing

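No paired analysis was possible because the only file is 1 domain list with no values per sample, so replicate numbers enter no test. Not run were windows at transcription starts, the alternatives for zinc finger exons, sequence content and width against score, and those for comparisons of times. The 5 alternatives to the shift test on all protein-coding genes left the ratio below 1 with p under 0.05, as did the alternatives for the share of domain bases in gene bodies, and clustering passed under both of its alternatives. Keeping domains at or above the median width left 14284 domains, 109.1 Mb and a median of 4.65 kb by construction, with 9.91% of X, 6.03% of the highest and 1.83% of the lowest autosome covered. Merging gave 141.5 Mb and 3.15 kb, autosomes alone 113.9 Mb and 2.85 kb, and leaving out domains at the first base, chosen after the data were seen, 118.5 Mb. After the first 3 Mb, coverage was 9.26% on X, 5.43% on the highest and 2.69% on the lowest autosome. In 10 Mb at the chromosome ends it was 6.86% beside centromeres and 3.08% at the far ends. The zinc finger ratio reversed to 1.52 against length-matched genes. It was 1.17 under Fisher's exact test (adjusted p = 0.246), 0.885 for at least 50% of the body covered (adjusted permutation p = 1) and 0.828 at gene ends (adjusted p = 0.557), and over all its alternatives adjusted p ran from 0.0008 to 1. Lists above expectation numbered 3 under Fisher's test (germline, clustered xenobiotic and secreted protein, and long neuronal genes) and 4 with length matching (germline, clustered xenobiotic and secreted protein, zinc finger and vomeronasal receptor genes). Fisher's test takes no account of length, and the matched genes of the vomeronasal list include olfactory receptor genes. Lists below numbered 4 of 16 on autosomes, where bivalent regulators lost the call and the X-linked list could not be tested, and 5 under Fisher's test (olfactory receptor, X-linked testis, Hox, ribosomal protein and histone genes). They numbered 1 for at least 50% of the body covered, 3 for wider domains, 3 with neighbours counted as 1, 0 at gene ends (3 at an unadjusted p under 0.05) and 1 with length matching. The last was the olfactory receptor list, where the draw may have run out of other genes. Length matching and gene ends were chosen after the data were seen. Length matching and Fisher's test each change the reference and drop the clustering that shifts keep; the cause of the reversal and of the other changes was not tested. Depth sets no stated limit here, as the list carries none.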

Other observations

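All tests in this part were chosen after the data were seen.

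Noncoding gene classes differed in their overlap with H4K20me3 domains. Pseudogenes overlapped more than shifted positions, with 909 of 9762 against 703.1 ± 28.7 (SD over 10000 shifts, ratio 1.29, adjusted permutation p = 0.0008 over 12 classes). Shifts place domains in protein-coding gene bodies more often than the list does (38.7% against 16.6% of domain bases). Sequence outside those bodies therefore lies above shifts as a whole. Pseudogenes were not compared with other such sequence, so the ratio does not set them apart from it. Transcribed pseudogenes had a ratio of 1.26 (75 of 467, adjusted permutation p = 0.0955). Genes of microRNAs and tRNAs lay well below, with 12 of 1228 (ratio 0.216, adjusted permutation p = 0.0008) and 3 of 403 (ratio 0.157, adjusted p = 0.00960), and long noncoding RNA genes stood at 0.770 (1684 of 12609, adjusted p = 0.0008). Immunoglobulin and T-cell receptor V segments overlapped in 10 of 374 cases (ratio 0.550, adjusted permutation p = 0.319), and none of 82 J segments did, where shifts gave 3.68 ± 4.70 (adjusted p = 0.609).

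Families of protein-coding genes that share a symbol root and have at least 15 members were compared with shifted positions only, where protein-coding genes as a whole stood at a ratio of 0.519. Of 153 families, 46 overlapped fewer domains than shifted positions at an adjusted p under 0.05 and none overlapped more (1 at an unadjusted p under 0.05). Families with no overlapping member included the nucleoporins named Nup (0 of 21, adjusted permutation p = 0.00255), the histone demethylases named Kdm (0 of 17, adjusted p = 0.00255), and the mitochondrial ribosomal proteins named Mrpl (0 of 49, adjusted p = 0.0137). These p values are against shifts and do not set a family apart from protein-coding genes as a whole. The highest ratio was in Nlrp genes, several of which act in oocytes, with 10 of 18 (ratio 1.71, adjusted permutation p = 0.205). Serpina genes followed with 5 of 24 (ratio 1.55, adjusted permutation p = 0.669), and cytochrome P450 genes named Cyp with 37 of 99 (ratio 1.53, adjusted permutation p = 0.0695, the family with the unadjusted p of 0.0218).

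Gene-poor chromosomes may hold more domains per Mb. Over 20 chromosomes, domains per Mb and protein-coding genes per Mb had a Pearson r of -0.467 (permutation p = 0.0383) and a Spearman rho of -0.412 (permutation p = 0.0713), both with an adjusted p of 0.0713 over the 2 coefficients. Without chromosomes 7 and 11, the farthest from the median gene density, r was -0.457 (permutation p = 0.0570) and rho -0.354 (permutation p = 0.151). Over the 19 autosomes r was -0.406 (permutation p = 0.0852) and rho -0.314 (permutation p = 0.192). The test leaves the relation open.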
